A study of Danio rerio with 9 samples.

How the data were processed

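Chromatin accessibility had been profiled by ATAC-seq in zebrafish (Danio rerio) spermatozoa, from males 7 days after a cardiac cryoinjury and from uninjured males. In ATAC-seq the Tn5 transposase inserts sequencing adapters into accessible DNA, so that reads accumulate where chromatin is open. Per the labels' protocols, each library was made from 100000 spermatozoa and sequenced as 100 bp paired-end reads on a NovaSeq instrument. The labels name 5 libraries from injured and 4 from uninjured males and give no batch. They do not say whether each library came from a separate male, so the p-values below measure only the spread between these libraries, which may be technical.

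The values used were the authors' deposited peak lists, 1 per library, each with positions and a peak score. The submitters' processing notes name Trim Galore, Bowtie2, SAMtools, Picard, MACS2, DiffBind, DESeq2, ChIPseeker, deepTools and bedtools and the genome build GRCz11, without versions, settings or order. How reads were shifted for the transposase, how duplicates and multiply mapping reads were treated, and the peak threshold are not given in the sources used here. The lowest deposited score was 13 in every list. That is the whole part of 10 times the -log10 of 0.05, but no source states the scale, so the score was used to rank peaks within a list and, in the closing section only, for ratios between regions of the same library. Ties were ordered by width and then by position. The lists held 0 mitochondrial entries and 0 overlapping peaks within a list, and positions differed by at least 33099 peaks between any 2 lists, so no library had been entered more than once.

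Read depth per library is unknown, because the lists carry no read totals. The labels give a target of 30 to 35 M reads per library and a range of 4.6 to 29 M reads retained after quality control, without tying a value to a library. A longer list can follow from a deeper library. For that reason each comparison was made on the lists as deposited and on equal-length lists, which hold the 15508 best-ranked peaks of each library, 15508 being the length of the shortest list. Holding the length equal does not remove every effect of depth, since the rank of a weak peak is noisier in a shallow library.

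Values per library were compared by an exact two-sided permutation test of the difference of means over all 126 assignments of the 9 libraries, for which the smallest possible p is 0.00794. For the lists as deposited 16 values per library were compared in this way, and for the equal-length lists 15, with Benjamini-Hochberg adjustment within each kind of list. The number of peaks and the covered length were fixed as main results before the data were examined, and the other values were added afterwards. Similarity was the Jaccard index in base pairs, tested by an exact one-sided permutation of within-group minus between-group pairs. Its chance level came from 20 sets of lists shifted circularly along each chromosome.

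Peaks that overlapped by at least 1 bp were merged across libraries into regions, and a region counted as detected in a library that had a peak in it. Regions detected in 2 to 7 libraries were compared between groups by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. The count fixed as the main result was that of regions detected in every library of one group and in none of the other, called group-exclusive here. The regions named are the first 5 in each direction in the equal-length comparison, ordered by p, difference in detection and median rank within the lists. Windows of 1 Mb with at least 18 peaks summed over the libraries were compared by the exact permutation test on the percentage of peaks they held. The windows, the chromosome shares, the boundary at 25 Mb on chromosome 4, the first 100 kb of chromosomes, the 25 strongest shared regions and the score ratios were chosen after the data had been seen.

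The region test was tested on simulated detection with the real libraries' detection rates, in which 200 of 47435 regions (lists as deposited) or 200 of 25551 regions (equal-length lists) were made to differ. All 200 were recovered as group-exclusive when detection was complete in one group and 0 in the other. With detection probabilities of 0.9 and 0.1 the share recovered was 38.5% and 37.5%. Among the regions not made to differ, 171 and 182 came out group-exclusive in these 2 simulations of the lists as deposited (3 and 5 injured, 168 and 177 control) and 54 and 48 in those of the equal-length lists (22 and 18 injured, 32 and 30 control). Adjusted p-values passed the 0.05 threshold for 0 regions in each of these simulations, so the adjusted test made no calls with 200 regions changed.

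Alternatives were stricter lists of the better-ranked 50% of peaks, chromosomes 1 to 25 only, other definitions of a region, leaving out each library in turn, and a block by the replicate number. No genome or annotation of GRCz11 was used here, and the gene tables at hand follow another build, GRCz12tu. Therefore 6 results fixed beforehand were not computed, namely both comparisons of promoters, the share of peaks at promoters, both tests of gene lists and the share of peaks with transcription factor motifs. Regions are given by coordinate only, counted from 1, with no statement on genes. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.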

Results

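Accessible regions were mapped in spermatozoa of 5 libraries from males collected 7 days after cardiac cryoinjury, a freezing lesion of the heart, and of 4 libraries from uninjured control males. The comparison asks whether an injury to the heart is accompanied by a different chromatin accessibility in sperm. The lists held 253847 peaks in all. The injured libraries 1 to 5 had 29622, 25718, 15508, 24018 and 17613 peaks, and the control libraries 1 to 4 had 31611, 34354, 30126 and 45277. Depth per library is unknown, so a site without a peak is one not detected in that library, not one shown to be closed.

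Fewer peaks had been called in sperm of injured males. The mean was 22496 ± 5834 peaks (SD, n = 5) in injured and 35342 ± 6851 (SD, n = 4) in control libraries, a ratio of 0.637, and every control list was longer than every injured list (exact permutation p = 0.0159). Adjusted over the 16 values per library that were compared, p was 0.127. Without control library 4 the difference was -9535 peaks in place of -12846, and the exact permutation p, over fewer assignments, was 0.0536. Median peak width was 245 ± 37.9 bp (SD, n = 5) and 228 ± 22.4 bp (SD, n = 4), which differed by less than the spread between libraries (exact permutation p = 0.429).

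Peaks covered 6.78 ± 1.55 Mb (SD, n = 5) in injured and 10.3 ± 2.66 Mb (SD, n = 4) in control libraries (exact permutation p = 0.0317, adjusted p = 0.127). Among the 15508 best-ranked peaks of each library the covered length was 5.21 ± 0.478 Mb (SD, n = 5) against 5.601 ± 0.571 Mb (SD, n = 4), within the spread between libraries (exact permutation p = 0.302). The call for the lists as deposited was also lost when control library 4 (difference -2.32 Mb, exact permutation p = 0.107), control library 2 (-3.40 Mb, p = 0.0714) or injured library 1, 3, 4 or 5 (-3.68, -3.14, -3.66 and -3.12 Mb, each p = 0.0857) was left out. The test then has fewer assignments and coarser steps of p. Without injured library 1 or 4 the difference was larger than the -3.52 Mb over all libraries, so the loss there does not come from a smaller difference.

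**Figure D1:**
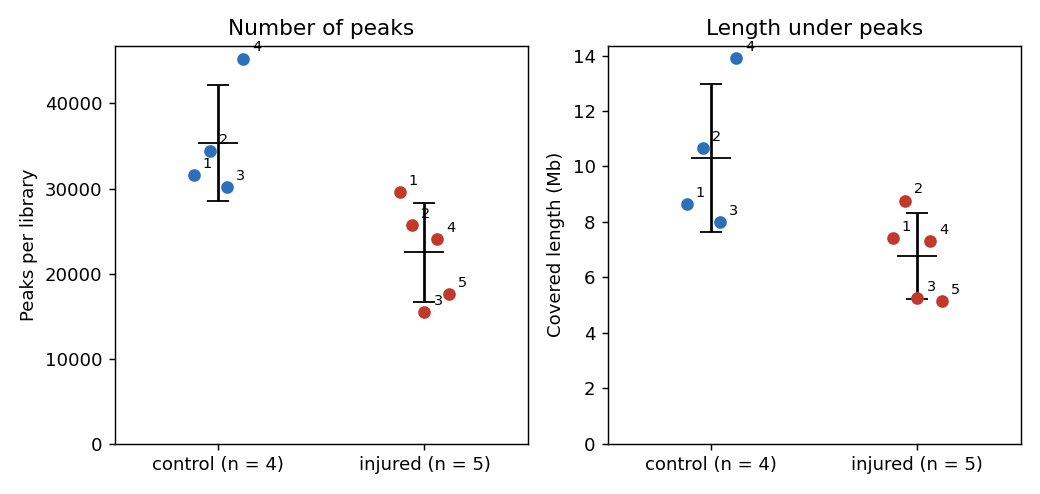
Number of peaks (left) and length under peaks in Mb (right) per library, for 4 control (blue) and 5 injured (red) libraries, with points numbered by replicate and bars for mean ± SD. The longest injured list has 29622 peaks and the shortest control list 30126.

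Sperm of both groups shared a small core of regions, which held most of the 1000 best-ranked peaks of each library. Merging gave 126838 regions, of which 1893 (1.49%) were detected in all 9 libraries and 79403 (62.6%) in 1 library. On chromosomes 1 to 25, 1617 regions were common to all 9 libraries, against 0 in each of 20 sets of shifted lists. Shifted lists test only whether peaks recur at the same places, not whether open chromatin or the mapping of reads put them there. Of the 1000 best-ranked peaks of a library 99.3% ± 0.791 (SD, n = 9) lay in a region detected in another library, and of the 1000 last-ranked peaks 41.6% ± 7.68 (SD, n = 9). In regions detected in all 9 libraries lay 64.7% ± 10.2 (SD, n = 9) of the best-ranked and 0.7% ± 0.811 (SD, n = 9) of the last-ranked peaks.

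Chromosome 4, whose long arm is known as late-replicating and rich in repeats, held the most peaks of any chromosome in 9 of 9 libraries. It carried 29.3 peaks per Mb on average, followed by chromosomes 16 and 10 with 25.2 and 24.9 peaks per Mb, and chromosome 9 had the fewest with 10.8. Its share was 8.69% ± 1.07 (SD, n = 5) of peaks in injured and 7.75% ± 0.656 (SD, n = 4) in control libraries, which did not exceed the spread (exact permutation p = 0.175). In the equal-length lists the shares were 9.57% ± 1.19 (SD, n = 5) and 9.44% ± 0.939 (SD, n = 4; exact permutation p = 0.849). Chromosome 4 held 15.2% of the regions detected in all 9 libraries but 6.29% of those detected in 1. Over the 25 chromosomes 0 shares differed at an unadjusted p below 0.05 by the exact permutation test in either kind of list, with lowest adjusted p of 0.918 and 0.762.

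Within chromosome 4 the equal-length lists were denser past 25 Mb on average, but in injured libraries not at the far end. There were 22.2 ± 3.87 peaks per Mb past 25 Mb and 12.1 ± 1.15 before it in injured libraries (SD, n = 5). Control libraries had 23.1 ± 2.48 and 9.53 ± 0.680 peaks per Mb (SD, n = 4). From 70 to 75 Mb there were 9.72 ± 2.09 peaks per Mb in injured (SD, n = 5) and 11.1 ± 2.22 in control libraries (SD, n = 4). The injured mean lay below that before 25 Mb, whereas the control mean lay above it. Both were lower than in the first 5 Mb, with 16.3 ± 2.82 (SD, n = 5) and 13.5 ± 2.09 (SD, n = 4). In the lists as deposited the contrast was smaller, with 26.7 ± 6.93 peaks per Mb past 25 Mb and 20.8 ± 6.65 before it in injured (SD, n = 5) and 36.4 ± 5.74 and 31.8 ± 7.23 in control libraries (SD, n = 4), and injured library 2 was less dense past 25 Mb (ratio 0.841). The difference between groups in the first 25 Mb at equal length (exact permutation p = 0.0159) did not pass adjustment over the 15 values compared (adjusted p = 0.238). It was 0.748 peaks per Mb in the better-ranked 50% of those lists (exact permutation p = 0.143), in place of 2.58, and had the opposite sign in the lists as deposited (exact permutation p = 0.0635). The equal-length lists reach down to scores of 13 to 31 in injured and 29 to 42 in control libraries, so their lower ranks are not equivalent.

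**Figure D2:**
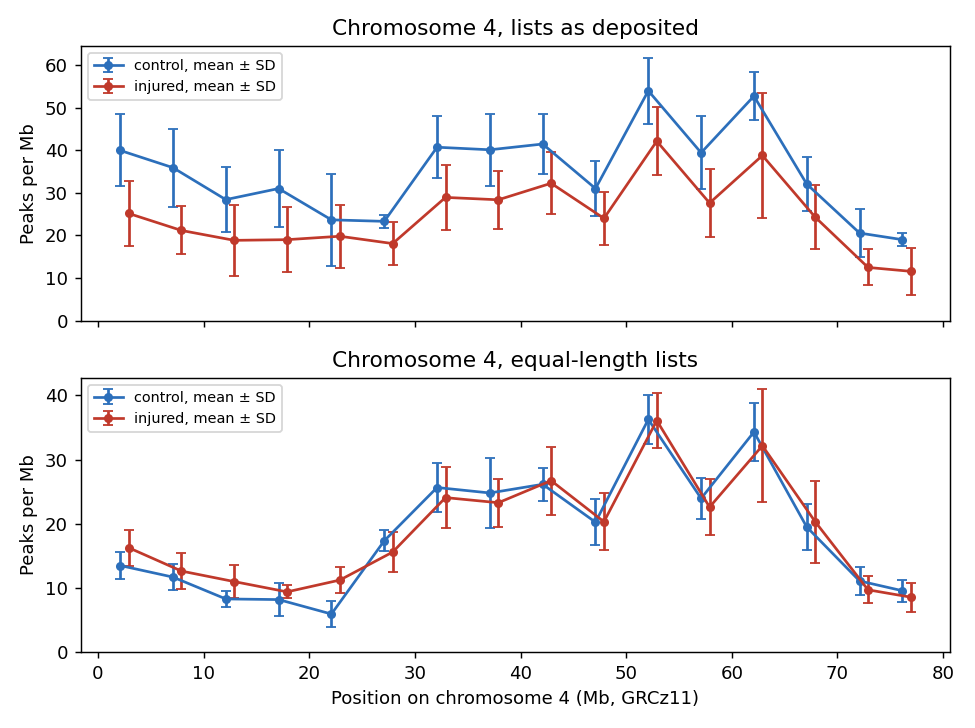
Peaks per Mb (vertical axis) in 5 Mb windows along chromosome 4 (horizontal axis, Mb, GRCz11) for the lists as deposited (top) and the equal-length lists (bottom), as mean ± SD of 4 control (blue) and 5 injured (red) libraries, drawn slightly apart. At equal length the injured mean lies above the control mean in the first 25 Mb (12.1 against 9.53 peaks per Mb), whereas as deposited it lies below (20.8 against 31.8).

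Similarity within groups did not exceed that between groups by more than chance. In the equal-length lists the Jaccard index averaged 20.8% within groups and 20.9% between groups, a difference of -0.0801 percentage points (exact one-sided permutation p = 0.5). The difference was 0.597 in the lists as deposited (exact permutation p = 0.119). At equal length without 1 library it ranged from -1.03 (without control library 3) to 0.864 (without injured library 1, exact permutation p = 0.0857), above 0 without any 1 injured library and below 0 without any 1 control library. The within-group mean pools 10 injured pairs with 6 control pairs, which were more alike. Leaving out a library changes that mix, so these signs partly follow from the pooling. In the equal-length lists the mean index of a library to the others was 19.98% ± 1.58 (SD, n = 5) in injured and 21.99% ± 0.863 (SD, n = 4) in control libraries (exact permutation p = 0.0317, adjusted p = 0.238), and in the lists as deposited 16.7% ± 0.861 (SD, n = 5) and 17.2% ± 0.191 (SD, n = 4; exact permutation p = 0.302). At equal length pairs of control libraries were the most alike, at 23.8% ± 2.49 (SD, 6 pairs), and pairs of injured libraries the least, at 19.1% ± 1.67 (SD, 10 pairs), with 20.9% ± 2.25 (SD, 20 pairs) for mixed pairs. Equal length keeps all 15508 peaks of injured library 3 but only the better-ranked part of control lists of 30126 to 45277 peaks. Better-ranked peaks recurred more often between libraries. How far this alone makes control libraries more alike at equal length was not tested. The 36 pairs ranged from 15.8% to 27.5%. As deposited, injured and mixed pairs were about as alike, at 16.7% ± 1.01 (SD, 10 pairs) and 16.7% ± 1.47 (SD, 20 pairs). Control pairs had 18.2% ± 1.33 (SD, 6 pairs). For 3 pairs of equal-length lists shifted along the chromosomes the mean index was 0.199%, against 21.2% for the same pairs unshifted.

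**Figure D3:**
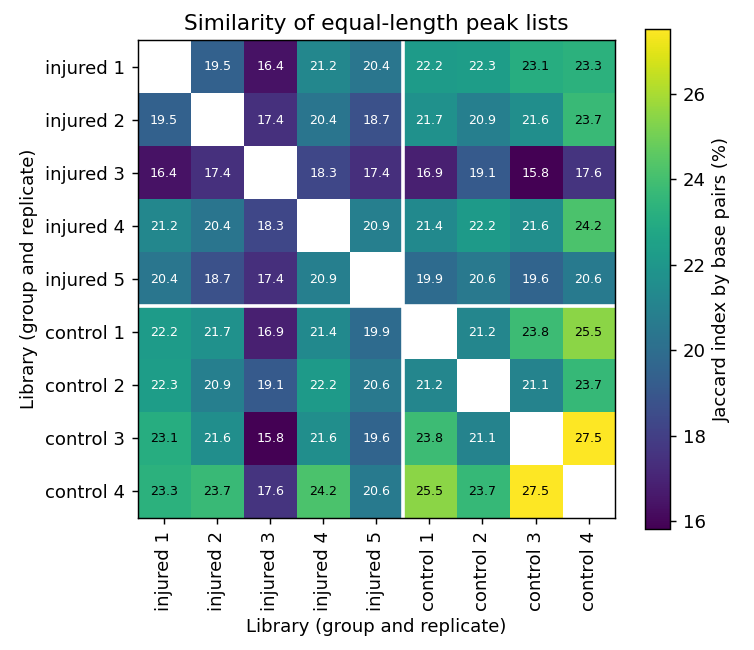
Jaccard index in base pairs (percent, colour scale and numbers) for each pair of the 9 equal-length lists, with libraries by group and replicate on both axes and white lines between the groups. The highest value, 27.5%, joins control libraries 3 and 4, and the lowest, 15.8%, joins injured library 3 and control library 3.

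Regions detected in 1 group alone were mostly control regions. In the lists as deposited 154 regions were detected in all 4 control and in 0 injured libraries, and 6 in all 5 injured and in 0 control libraries. Equal chance for every library would give 45.7 and 29.3, but the control lists were longer, and simulations with the libraries' own detection rates gave 168 and 177 control-exclusive and 3 and 5 injured-exclusive regions among those not made to differ. In the equal-length lists the counts were 49 and 8, with 22.8 and 15.98 from equal chance and 32 and 30 control-exclusive and 22 and 18 injured-exclusive regions in the simulations. The simulations did not hold fixed the number of libraries in which each region was detected. In 100 detection matrices that did, injured-exclusive regions numbered 4 to 25 (mean 10.9), so 8 was not a deficit. Control-exclusive regions numbered 23 to 48 in those matrices. Leaving out any 1 library gave 213 to 589 group-exclusive regions in place of 160 as deposited, and 83 to 209 in place of 57 at equal length, since fewer libraries then have to agree.

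Among the equal-length lists the control-exclusive regions first in order lay on chromosome 17 (3016707 to 3016922), chromosome 12 (41344671 to 41344974), chromosome 3 (62549563 to 62549829), chromosome 8 (53366558 to 53367030) and chromosome 2 (49158668 to 49159044), in GRCz11. Each was detected in 4 of 4 control and 0 of 5 injured libraries (Fisher's exact p = 0.00794, adjusted p = 1). In the full lists those on chromosomes 17, 3 and 8 still had a peak in 0 injured libraries, and those on chromosomes 12 and 2 had a peak in 1. The injured-exclusive regions first in order lay on the unplaced scaffold KN150240.1 (5082 to 6331), chromosome 5 (69543923 to 69544159), chromosome 22 (7617406 to 7617791), the alternate contig ALT_CTG5_1_47 (86139 to 86815) and chromosome 13 (11401616 to 11402366). Each was detected in 5 of 5 injured and 0 of 4 control libraries (Fisher's exact p = 0.00794, adjusted p = 1). In the full lists the scaffold region had a peak in 0 control libraries, whereas the others had a peak in 1 (chromosome 5), 3 (chromosome 22), 4 (the alternate contig) and 2 (chromosome 13). Of the 49 control-exclusive regions, 25 stayed so in the full lists, and of the 8 injured-exclusive regions, 1. The full control lists add more peaks than the full injured lists, so an injured-exclusive region has more chances to lose that status and the shares are not comparable.

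Fisher's exact test with Benjamini-Hochberg adjustment called 0 of 44043 regions in the lists as deposited, where the lowest adjusted p was 0.753, and 0 of 23147 in the equal-length lists, where it was 1. At an unadjusted p below 0.05 there were 1974 regions as deposited, 94 detected more often in injured and 1880 more often in control libraries. At equal length there were 718, with 156 and 562. Among all regions tested as deposited, 10497 were detected more often in injured and 33546 more often in control libraries. At equal length these numbers were 8930 and 14217. A surplus on the control side was therefore present among the tested regions irrespective of p. The adjusted test also called 0 regions in simulations with 200 completely different regions, so these counts of 0 do not show that the regions are alike.

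**Figure D4:**
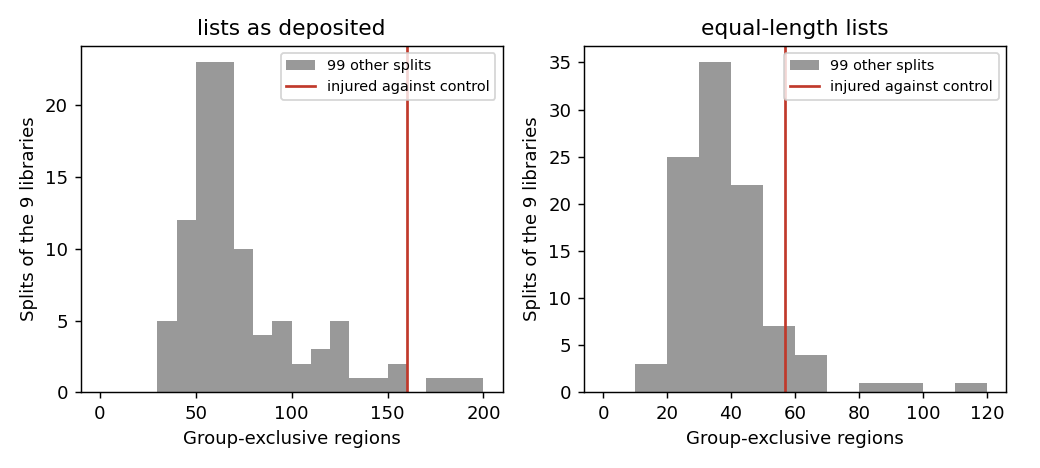
Number of group-exclusive regions (horizontal axis) in 99 other splits of the 9 libraries into 5 and 4 (grey, number of splits on the vertical axis) and in the real split (red line), for the lists as deposited (left) and the equal-length lists (right). The real split gives 160 and 57 regions, and the highest of the other splits drawn give 197 and 110.

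On the scale of 1 Mb, 59 of 1308 windows differed in their share of the equal-length lists at an unadjusted exact permutation p below 0.05, 29 with a higher share in injured and 30 with a higher share in control libraries, and 0 did after Benjamini-Hochberg adjustment (lowest adjusted p = 0.993). By p and then by size of the difference, the first window more occupied in injured libraries lay at 25 to 26 Mb of chromosome 7, with 19.2 ± 7.26 (SD, n = 5) against 7.25 ± 2.75 peaks (SD, n = 4; exact permutation p = 0.00794). Next came 21 to 22 Mb of chromosome 4, with 16.4 ± 3.44 (SD, n = 5) against 7.00 ± 2.83 peaks (SD, n = 4; exact permutation p = 0.00794). First among those more occupied in control libraries was 47 to 48 Mb of chromosome 19, with 11.4 ± 0.894 (SD, n = 5) against 16.5 ± 3.11 peaks (SD, n = 4; exact permutation p = 0.0159). In the lists as deposited 56 of 1352 windows passed unadjusted and 0 after adjustment. Such unadjusted counts were common under other groupings of the libraries. At equal length 26 of 100 splits gave at least 59 windows (median 45.5), and as deposited 64 of 100 gave at least 56 (median 61.5). The smallest possible p of the exact permutation test is 0.00794, so a window could pass adjustment only if many windows reached that value. These counts of 0 therefore do not show that the windows are alike. At equal length, leaving out any 1 library gave 11 to 42 windows in place of 59. Fewer assignments are then left, so p moves in coarser steps and fewer windows can pass by chance alone.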

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

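In this part the tests of the splits of the libraries and the value per library of control library 4 were chosen after the results had been seen. The count on chromosomes 1 to 25 had been planned, but its use against an explanation was set out after it was seen. The comparison with matrices of fixed margins was set out before its result was seen.

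In control library 4, 63.7% of the regions in the list as deposited were also detected in another library, lower than in the other control libraries, of which the nearest had 66.2%. The gap took up 0.888 of the range of the 4 values. It is 1 such case among 74 groups of values examined, where chance alone would give about 3.7. This library also has the longest list, 45277 peaks.

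The first pattern is the lower number of peaks in injured libraries. Peaks on alternate contigs and unplaced scaffolds do not account for it, since on chromosomes 1 to 25 the exact permutation p was 0.0238. Shallower or less complex injured libraries cannot be told apart from a loss of accessible sites after the injury, because no read total is tied to a library. The 6 injured-exclusive and 154 control-exclusive regions both lay within the range of 100 detection matrices with the same list lengths and the same number of libraries per region (0 to 10 and 134 to 206). A count of 154 inside that range had been set beforehand as evidence against a loss of sites, but that bound was wrong: a general loss would shorten the lists, and the list lengths are held fixed in those matrices.

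The second pattern is the surplus of control-exclusive regions when list length is held equal. The 49 regions lay just above the 23 to 48 of the 100 matrices with the same margins (mean 31.7 ± 5.22, SD). That narrowly met the bound set beforehand against list lengths and detection rates as the whole cause. The matrices do not keep any likeness between particular libraries, so other sets of libraries may exceed them too. Equal length does not equalise depth, as the lists reach down to scores of 13 to 31 in injured and 29 to 42 in control libraries. Unequal depth is therefore not excluded. In the number of group-exclusive regions of both directions together, the grouping by injury was not exceptional, however. Of 100 splits of the libraries, the real one included, 10 gave at least 57 such regions, with up to 110 in another split, so chance is not excluded. That count does not test the 49 control-exclusive regions by themselves. A biological difference between the groups stays untested beyond this.

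For the lists as deposited 4 of 100 splits, the real one included, gave at least its 160 group-exclusive regions, and the highest other gave 197. That share is below 0.05, but it is 1 of 4 such comparisons without adjustment, chosen after the results had been seen. This single count is therefore weak evidence against chance and does not exclude it. The difference in list length is not excluded, since the counts in both directions lay within the range of the matrices with the same margins. Among all 126 splits there were 5 as high as deposited and 12 at equal length. The highest, with 240 and 119 regions, set injured library 2 together with control libraries 1, 3 and 4. For the 1 Mb windows 26 of 100 splits gave at least 59 windows at equal length (highest other 118), and 64 of 100 gave at least 56 as deposited (highest other 132), so chance is not excluded for either.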

How the results depend on the processing

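The stricter, chromosome-only, region, replicate and block alternatives were chosen before the data were examined. Those for covered length at equal length, peaks covering 50% of a region, chromosome 4 and the windows were chosen afterwards. The number of peaks kept its direction in 12 of 12 alternatives and its side of the threshold in 10. For 1 of these, the better-ranked 50% of each list, both were kept by construction, so it tests nothing about the number. Without 1 library the difference ranged from -14627.8 to -9534.53 peaks, with p = 0.0536 without control library 4 by the exact permutation test. Covered length kept its direction in all 13 and its call in 5. It ranged from -4.29 to -2.32 Mb without 1 library, where fewer assignments are left to the test, and was -0.387 Mb at equal length. Group-exclusive regions numbered 101 in the better-ranked 50% and 85 where peaks had to cover 50% of the region, against 160 as deposited, and 213 to 589 without 1 library. At equal length they numbered 21 in the better-ranked 50%, against 57, and 83 to 209 without 1 library. The windows numbered 34 in the better-ranked 50% and 11 to 42 without 1 library, against 59. The difference in the first 25 Mb of chromosome 4, 2.58 peaks per Mb at equal length, was 0.748 in the better-ranked 50% and -11.0 in the lists as deposited, which are of unequal length. The cause of these shifts was not tested, except that group-exclusive regions become more numerous without 1 library because fewer libraries must agree. For the windows, the coarser steps of p without 1 library lower the count by themselves, to an extent that was not tested. The chromosome 4 share (13 alternatives) and the similarity of the groups (14) stayed without a call. Demanding an overlap of 50% of the shorter of peak and region, or a region in at least 3 libraries, moves nothing by construction.

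The replicate numbers are shared by 4 pairs, but same-numbered libraries correlated only between -0.0587 and 0.0449 in their detection. Libraries of different number spanned a like range, from -0.0402 to 0.0618. At equal length 2 of 8 libraries correlated best with their own number, namely injured and control library 4. These values gave no sign that a shared number joins libraries, but they do not exclude a shared batch. With the replicate number as a block the differences were -11625.5 peaks, -3.12 Mb covered and 2.53 peaks per Mb in the first 25 Mb of chromosome 4, none past the threshold, as 4 pairs cannot give p below 0.125. Group-exclusive regions over the 4 pairs numbered 213 as deposited and 83 at equal length, which equals leaving out injured library 5, as no pairing enters that count. The alternatives for promoters, gene lists and motifs were not run, since those results need an annotation or sequence of GRCz11. Depth limits every count of detected regions and is unknown per library.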

Other observations

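The strongest shared regions, the chromosome ends and the score ratios below were examined only after the data had been seen, and so were the tests on them and on the chromosome 4 share.

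Some of the regions ranked highest by peak score in both groups lay at chromosome ends and on unplaced scaffolds. Whether reads that map to several places raise their scores was not tested. Of the 25 regions ranked highest in all 9 libraries, 8 lay within 100 kb of a chromosome start or of the farthest peak on a chromosome and 6 on unplaced scaffolds. The region ranked first was at 53384678 to 53384897 of chromosome 17 (GRCz11), 220 bp wide, and its lowest rank percentile in any library was 99.99. The first 100 kb of the chromosomes held 0.387% ± 0.0442 (SD, n = 5) of chromosomal peaks in injured and 0.344% ± 0.0399 (SD, n = 4) in control libraries (exact permutation p = 0.167), on average 1.98 times their share of the length. They held 19 of the 1617 chromosomal regions detected in all 9 libraries.

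Over both groups the densest 1 Mb window of the equal-length lists lay at 12 to 13 Mb of chromosome 24, with 68.6 ± 17.7 peaks (SD, n = 5) in injured and 75.3 ± 9.60 (SD, n = 4) in control libraries (exact permutation p = 0.540). Next was 53 to 54 Mb of chromosome 4, with 67.8 ± 7.26 (SD, n = 5) and 71.0 ± 2.16 peaks (SD, n = 4; exact permutation p = 0.429).

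The third pattern is a set of strong regions whose peak scores kept nearly the same ratio in every library. In the chromosome 24 window 4 of the 25 strongest regions lay close together, at 12368715 to 12369975, 12378829 to 12380236, 12410080 to 12411760 and 12415949 to 12416829. Within a library their scores had ratios that varied by a median coefficient of variation of 6.40% over the 9 libraries, against 49.3% for ratios to the other strongest regions. The scale of the score is not stated, so these ratios are not ratios of signal. Regions far away kept similar ratios to them, at 15112250 to 15115698 of chromosome 11 (4.65%), 15657967 to 15658973 of chromosome 16 (5.62%), 11486948 to 11488567 of chromosome 15 (6.81%) and 5313 to 8209 of the scaffold KN150160.1 (7.95%). A candidate explanation is 1 shared source of reads, such as copies of a sequence among which reads are divided, for which a variation as low as 6.40% would be seen; sites that are opened together could give stable ratios too, and without the sequence these stay open.

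Chromosome-end regions were less uniform. Over all 8 the median coefficient of variation of score ratios was 36.5%, against 48.4% for ratios to the chromosome 24 regions, so by this pooled value a single source for all of them was neither borne out nor excluded. Both regions of chromosome 17 (medians of 47.4% and 52.8% to the other end regions) and that of chromosome 3 (37.6%) had no stable ratios. Their values argue against a single source for all 8. For the other 5, at chromosomes 10, 13, 6 (both ends) and 2, the medians were 6.83% to 8.21%, a subset picked from these same values. Of 13 other strongest regions, 5 had medians of 4.75% to 7.96% to that subset. Of these, 3 lay past the 100 kb limit, 159 kb (chromosome 7), 150.1 kb (chromosome 12) and 209.6 kb (chromosome 18) from the farthest peak, and the others on unplaced scaffolds. The score of the chromosome-end regions relative to the chromosome 24 regions ranged from 0.154 to 0.643 between libraries and did not follow the groups (0.389 ± 0.164, SD, n = 5 injured, and 0.349 ± 0.161, SD, n = 4 control, exact permutation p = 0.722).

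The difference in the chromosome 4 share of peaks was 0.940 percentage points in the lists as deposited and 0.125 at equal length. It was 0.589 without injured library 4 and 1.62 in the better-ranked 50% of each list. As the first did not exceed the spread between libraries, no effect of list length on it could be decided.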
